A study of Mus musculus with 6 samples.

How the data were processed

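Gene expression was measured by RNA-seq in 6 libraries of c-Kit+ splenocytes, 1 per mouse. Per the labels' protocols, spleens were crushed, red blood cells were lysed, and cells bound by CD117 magnetic beads were collected. RNA with an integrity number above 8 was selected by its poly-A tail and made into strand-specific TruSeq libraries, with paired-end reads of 75 bases. The labels put 3 mice in a group named AML and 3 in a group named MPN. Replicate numbers were given in accession order, so they name mice and pair none.

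The TPM values were deposited by the authors per gene symbol, a measure scaled to transcript length, with the same sum in each library. Per the file headers, they are gene-level output of RSEM, with 1 column per mouse and no pooling. The RPKM values, reads scaled to gene length and library size, were deposited by the authors per Ensembl gene identifier. In those values 1 read had been added to every gene, as the low values show, so that unread genes sit at a common floor. TopHat2, RSEM, Bowtie2 and the mouse builds mm9 and mm10 are listed per the submitters' processing notes, which give no role or version. Which build belongs to which table is not given in the sources used here. TPM keeps no depth. In the RPKM table, low values lay within 0.05 of a whole multiple of the step that 1 read adds, and these steps gave the relative depth of the libraries. Counts of reads were not analysed here.

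The TPM table held 24054 genes, of which 17949 were above 0 in at least 1 library. A spreadsheet had turned 27 gene symbols into dates, and these were tested but never named. Per the file headers, MPN replicate 1 was sequenced in another run than the other 5 libraries. Gene positions were taken from GENCODE M21 on GRCm38 and serve for location only. In the RPKM table, 25213 of 25991 identifiers matched a symbol.

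Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, which left 12223. Values were used as log2(TPM + 1), with a pseudocount of 1, and AML was compared with MPN by limma 3.58.1 in R 4.3.3 with a mean-variance trend and no covariate. Tests were two-sided, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are therefore on the log2(TPM + 1) scale, which understates the change of genes with low values. TPM of the genes is given as mean and SD over 3 mice. A looser screen counted genes with at least a 2-fold change and an unadjusted p under 0.05. Dnmt3a, Flt3 and Kit were also compared by an exact two-sided permutation test, whose smallest possible p with 3 mice against 3 is 0.1.

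Gene lists, 25 in number, were fixed before the data were examined, from textbook markers of progenitors, of the mature cell types a spleen can hold, of signalling pathways and of cell stress. The sex-linked list served to check the mix of animals and got no set test. The other 24 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data. Genes were named by a rule fixed at the same time. It took the 12 largest log2 fold changes in each direction among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 5 TPM, then Dnmt3a, Flt3 and Kit, and the 4 members of each list with the smallest p. Predicted genes without a name and segments of antigen receptors, with the date-like symbols 221 of the called genes, were counted but not named. Other list members given below were chosen after their values were seen.

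The analysis was tested on simulated data for the 12223 genes of the comparison of AML with MPN, with 3 libraries per group. Of 100 genes changed 2-fold, 59% were called, and of 100 changed 4-fold, 91% were called, with 6 false calls. The fold was set on the log2(TPM + 1) scale, in genes with a mean above 2 on that scale. Far fewer genes were changed than passed in the real comparison. These shares therefore do not describe genes with low values or the real number of changed genes. Camera called 0 of 480 simulated lists without a change. The simulated genes varied independently, while the estimated correlation in the real lists reached 0.94, for MHC class II genes. The simulation therefore does not show how often camera at the preset correlation calls correlated lists wrongly.

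Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median scaling, quantile normalization, the RPKM table, limma without the trend and with array weights, camera on ranks and with an estimated correlation, and leaving out each mouse in turn. A fit with a term for sex was added after seeing the data. Because females occurred in the AML group only, this fit compares the male AML mouse, replicate 3, with the MPN mice, and assumes that it varies like the other mice. Transcripts that share sequence with a near-identical copy, such as the haemoglobin genes, Akr1c12, Sirpb1a, Hspa1a and Hspa1b, are uncertain, because reads could be split between the copies.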

Results

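The data set held RNA-seq profiles of c-Kit+ cells from the spleens of 6 mice. c-Kit, also called CD117, is a receptor tyrosine kinase of blood stem and progenitor cells, and magnetic beads against it had been used for the selection. All mice carried an internal tandem duplication (ITD) on both alleles of Flt3, a receptor tyrosine kinase of early blood cells. The 3 mice of the AML group (acute myeloid leukaemia) were moribund and carried Dnmt3a as 1 floxed and 1 null allele together with Mx-driven Cre recombinase. In the 3 MPN mice (myeloproliferative disease) both Dnmt3a alleles were floxed, and their titles name no Cre. The comparison asks which transcripts differ between these groups, whose alleles of Dnmt3a, a de novo DNA methyltransferase, differ beside Flt3-ITD. The titles do not say whether Cre had removed the floxed allele. Genotype, Cre and disease state changed together between the groups.

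Relative depth, read from the steps of the RPKM values, was 1.33, 1.03 and 0.758 for AML replicates 1 to 3, and 1.08, 1.01 and 0.961 for MPN replicates 1 to 3. Between 11780 and 12034 genes reached 1 TPM per library. Across genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.949 to 0.975 within AML, 0.982 to 0.992 within MPN and 0.856 to 0.923 between the groups. The first principal component held 72.9% of the variance and separated the groups. The 20 genes with the highest mean TPM took 8.47%, 11.2% and 12.2% of all transcripts in the AML mice and 16.4%, 16.1% and 17.9% in the MPN mice. Xist, the X-inactivation transcript, stood at 186 and 194 TPM in AML replicates 1 and 2 and at most 0.06 TPM elsewhere. The Y-linked Ddx3y was at most 0.01 TPM in those 2 mice and 27.1 to 48.5 TPM in the other 4, so female animals occurred in the AML group only. None of the 4 tested sex-linked genes passed over all genes, and 4 fell in AML when adjusted over the list alone, as they did over all genes without AML replicate 3 and with array weights.

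Dnmt3a mRNA fell in AML to 12.6 ± 1.02 TPM from 32.2 ± 2.53 TPM in MPN (SD, n = 3 each), which is 39.3% of the MPN level. The log2 fold change was -1.28 with a standard error of 0.13 and a limma adjusted p of 0.000879. In the RPKM table the AML level was 39.8% of MPN. Flt3 rose from 110 ± 2.86 to 167 ± 29.3 TPM, by 0.59 ± 0.14 (SE) on the log2 scale, with an adjusted p of 0.0179. This call ended under median scaling, with an adjusted p of 0.0605, and without MPN replicate 1, 2 or 3, with adjusted p of 0.0597, 0.0552 and 0.0605. Kit, the selection marker, did not pass, at 119 ± 17.3 TPM in AML and 147 ± 4.17 TPM in MPN (adjusted p = 0.103). For each of these genes the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 mice against 3 allow. On GRCm38, Dnmt3a (ENSMUSG00000020661) lies on chromosome 12 from 3806007 to 3914443 on the plus strand. Flt3 (ENSMUSG00000042817) lies on chromosome 5 from 147330741 to 147400489 on the minus strand, and Kit (ENSMUSG00000005672) on chromosome 5 from 75574916 to 75656722 on the plus strand. Values per gene do not show which exons were read, so a transcript lacking the floxed exons still counts as Dnmt3a.

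**Figure D1:**
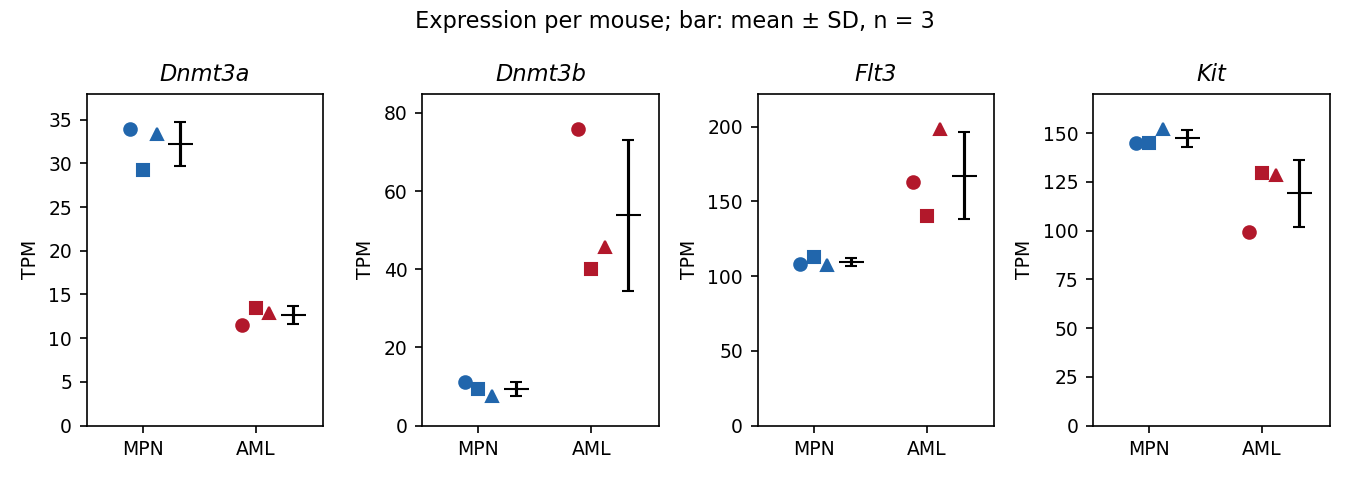
TPM of Dnmt3a, Dnmt3b, Flt3 and Kit in each mouse, with MPN in blue and AML in red, replicates 1, 2 and 3 as circle, square and triangle, and bars for the mean ± SD (n = 3). Dnmt3a averaged 12.6 TPM in AML and 32.2 TPM in MPN, and Dnmt3b averaged 53.8 and 9.45 TPM.

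Between AML and MPN, most tested haematopoietic stem cell markers, STAT5 target genes and Hox and Meis genes rose, and most tested interferon-stimulated genes and markers of macrophages, B cells, T and NK cells, dendritic cells, monocytes and neutrophils fell. These lists passed camera at the preset correlation, and 0 lists passed with an estimated correlation (adjusted p of 0.258 or more). Of 12223 genes tested, 3678 passed the limma threshold, with 2454 higher and 1224 lower in AML. Of these, 1657 changed at least 2-fold, 899 upward and 758 downward. Over all tested genes, called or not, the groups did not overlap for 50.9%, against 10% by chance with 3 mice against 3. At least 2-fold and unadjusted p under 0.05 held for 1803 genes, 933 higher and 870 lower in AML. The median log2 fold change of all tested genes was 0.13. Median scaling removes that shift, and it called 3621 genes, 1939 higher and 1682 lower, so the share of higher calls was 53.5% in place of 66.7%. Within the sequencing run that held 5 of the libraries, without MPN replicate 1, 2277 genes passed. Without MPN replicate 2 or 3, 2009 and 2280 passed, and with a term for sex, added after seeing the data and equal to setting the male AML replicate 3 against the MPN mice, 1208 passed. That fit draws the fold change from fewer mice, so a call can end while the fold stays about as large.

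**Figure D2:**
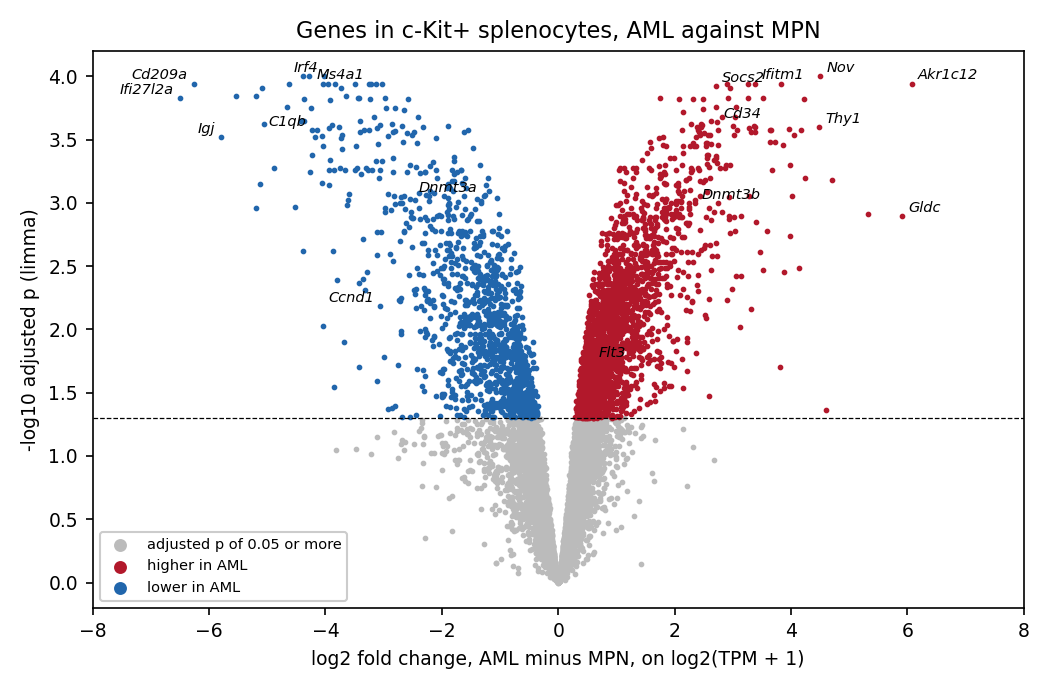
Log2 fold change (AML minus MPN, on log2(TPM + 1)) against -log10 of the limma adjusted p for 12223 genes, with the dashed line at an adjusted p of 0.05. The 2454 genes called higher in AML are red, the 1224 called lower are blue, and the rest are grey.

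Among the largest rises on the log2(TPM + 1) scale were Akr1c12, an aldo-keto reductase, at 126 ± 56.3 TPM in AML and 0.757 ± 0.215 TPM in MPN (log2 fold change 6.08 ± 0.33 SE, adjusted p = 0.000114), and Gldc, the glycine decarboxylase of mitochondria, at 86.8 ± 76.2 against 0.0367 ± 0.0115 TPM (5.91 ± 0.69, adjusted p = 0.00126). Nov, a secreted matricellular protein, reached 52.2 ± 10.2 TPM against 1.33 ± 0.215 TPM. Thy1, a surface glycoprotein of T cells and some stem cells, reached 141 ± 69.9 TPM against 4.86 ± 0.621 TPM. The transcription factor gene Mycn reached 76.1 ± 38.3 TPM against 2.97 ± 0.491 TPM. Plet1, Ecm1, Myl10, Gdf10 and Igfbp7 rose by log2 fold changes of 5.32, 4.24, 4.23, 4.13 and 4.02. Snora43 and Snord22, small nucleolar RNAs that lie inside host genes, also passed. Snora43 was listed at 0 in all MPN mice and averaged 29.2 TPM in AML, and neither passed in the RPKM table (adjusted p = 0.194 and 0.109). The Snord22 call also ended without any 1 of the mice other than MPN replicate 2 (adjusted p of 0.0534 to 0.145), with a term for sex (0.285) and with array weights (0.442). It ended as well with a pseudocount of 0.1, no filter, median scaling, quantile normalization and no trend (adjusted p of 0.0509 to 0.0808).

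Among the largest falls on the log2(TPM + 1) scale was that of Ifi27l2a, an interferon-induced gene, from 427 ± 129 TPM in MPN to 3.96 ± 2.22 TPM in AML (log2 fold change -6.50 ± 0.39 SE, adjusted p = 0.000149). Cd209a, a lectin of dendritic cells, fell from 230 ± 71.6 to 2.07 ± 1.21 TPM, and Igj, the joining chain of polymeric antibodies, from 342 ± 106 to 5.75 ± 3.75 TPM. The chemokine Ccl5 fell from 493 ± 174 to 18.6 ± 6.20 TPM. Klrd1, a receptor subunit of natural killer (NK) cells, fell from 139 ± 51.0 to 2.79 ± 1.15 TPM. Ncr1, Gzma and Klrb1c, of the T and NK cell list, averaged only 2.77, 1.75 and 1.51 TPM in MPN, and Klrb1c did not pass (adjusted p = 0.601). The level of Klrd1 is therefore no measure of how many NK cells were lost. Sirpb1a, Cxcl9, Apol7c, Spib, Cd7, Ms4a4c and Cadm3 had log2 fold changes of -5.54, -5.18, -5.13, -5.09, -5.05, -4.88 and -4.63.

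Of the 24 lists tested with camera, 14 passed at the preset correlation, 5 upward and 9 downward. None passed with an estimated correlation after adjustment, where 4 had an unadjusted p under 0.05, namely the macrophage, B cell, T and NK cell, and dendritic cell lists. Interferon-stimulated genes had the lowest median. Of 25 tested, 23 fell, 0 rose and 2 did not pass, and 24 fell when adjusted over the list alone. Their median log2 fold change was -2.59 (camera adjusted p = 4.9e-19, and adjusted p = 0.271 with an estimated correlation). Ifit3 fell from 32.0 ± 12.6 to 0.450 ± 0.108 TPM, Ifi44 from 24.6 ± 12.6 to 0.313 ± 0.189 TPM and Oas2 from 27.2 ± 5.94 to 1.25 ± 0.870 TPM.

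Markers of macrophages, B cells, and T and NK cells fell. Of 15 macrophage markers, 13 fell and 2 did not pass, and 14 fell when adjusted over the list alone (median -1.63, camera adjusted p = 1.1e-11, adjusted p = 0.258 with an estimated correlation). The complement genes C1qa and C1qb fell from 24.0 ± 8.60 to 0.373 ± 0.647 TPM and from 23.9 ± 7.99 to 0.347 ± 0.516 TPM. Of 9 B cell markers, 8 fell and 1 did not pass, and 8 fell when adjusted over the list alone (median -2.21, camera adjusted p = 1.9e-09, adjusted p = 0.260 with an estimated correlation). Ms4a1, which encodes CD20, had a log2 fold change of -3.22 ± 0.17 (SE), and Cd79a fell from 18.6 ± 0.988 to 0.830 ± 0.427 TPM. Of 17 T and NK cell markers, 13 fell, Thy1 and Lck rose, and 2 did not pass, with the same counts when adjusted over the list alone (median -1.55, camera adjusted p = 1.1e-06, adjusted p = 0.260 with an estimated correlation). Cd8a fell from 47.1 ± 9.65 to 1.38 ± 0.714 TPM and Cd4 from 25.8 ± 14.4 to 0.630 ± 0.173 TPM. Cd3d, Cd3e and Cd3g, which also fell, were low in MPN already, at 2.07 ± 0.695, 2.49 ± 0.835 and 3.53 ± 1.64 TPM. The levels of Cd8a and Cd4 are therefore no measure of how many T cells were lost. The call of the T and NK cell list ended with a filter at 5 TPM (adjusted p = 0.189) and in the RPKM table (adjusted p = 0.0690).

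Of 13 dendritic cell markers, 7 fell, Flt3 rose and 5 did not pass, and 9 fell and 1 rose when adjusted over the list alone (median -1.56, camera adjusted p = 1.3e-06, adjusted p = 0.271 with an estimated correlation). Irf4, a transcription factor of dendritic cells and lymphocytes, fell from 33.7 ± 4.03 to 1.13 ± 0.146 TPM. All 10 MHC class II genes fell, both over all genes and when adjusted over the list alone (median -2.12, camera adjusted p = 2.9e-06, adjusted p = 0.366 with an estimated correlation). H2-DMb2 went from 525 ± 162 to 78.2 ± 42.9 TPM, and Ciita, the transactivator of these genes, from 326 ± 24.3 to 61.0 ± 38.0 TPM. With a term for sex, 1 of the 10 passed, and Ciita did not (log2 fold change -2.0 against -2.70 without the term, adjusted p = 0.136). Of 16 monocyte markers, 10 fell, Cd14 rose and 5 did not pass, with the same counts when adjusted over the list alone (median -1.58, camera adjusted p = 1.6e-05, adjusted p = 0.271 with an estimated correlation). The Cd14 call ended without any 1 of the mice other than AML replicate 3 (adjusted p of 0.0776 to 0.163), with a term for sex (log2 fold change 0.36 against 0.74 without it, adjusted p = 0.496), and with no filter, a filter at 5 TPM, median scaling, quantile normalization and RPKM (0.0546 to 0.0872). Ctss, a lysosomal protease, fell from 912 ± 181 to 248 ± 132 TPM, and Cx3cr1, a chemokine receptor, from 16.3 ± 5.68 to 1.98 ± 2.04 TPM. Of 18 mature neutrophil markers, 11 fell, Padi4 rose and 6 did not pass, and 12 fell and 1 rose when adjusted over the list alone (median -1.16, camera adjusted p = 3.9e-06, adjusted p = 0.366 with an estimated correlation). Mmp9 fell from 72.4 ± 21.7 to 26.2 ± 1.90 TPM and Mmp8, likewise a collagen-degrading protease, from 49.7 ± 11.2 to 24.4 ± 1.21 TPM. With a term for sex, 2 neutrophil markers fell and 0 rose, with a log2 fold change of 1.01 and an adjusted p of 0.109 for Padi4.

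Erythroid genes as a list lay lower in AML (median -1.61, camera adjusted p = 7.4e-05, adjusted p = 0.589 with an estimated correlation). Of the 25 tested, only Klf1, an erythroid transcription factor, passed over all genes, at 13.2 ± 12.9 TPM in AML against 69.5 ± 24.6 TPM in MPN (adjusted p = 0.0424), and 0 passed when adjusted over the list alone. The Klf1 call ended without AML replicate 2 (adjusted p = 0.0690) and without MPN replicate 1, 2 or 3 (adjusted p = 0.106, 0.114 and 0.0874). It also ended with a pseudocount of 0.1 (adjusted p = 0.0586), with no filter (0.0794) and without the trend (0.0503). Gata1 stood at 10.7 ± 9.67 against 43.6 ± 17.0 TPM (adjusted p = 0.0523). It passed without AML replicate 1 (log2 fold change -3.04, adjusted p = 0.0166) and without AML replicate 3 (-1.45, adjusted p = 0.0399). It also passed with a pseudocount of 5, median scaling, quantile normalization, RPKM, array weights and a term for sex (adjusted p of 0.00275 to 0.0471). The AML mice differed among themselves in these genes, whose mean relative to the MPN mice was 0.52, -1.20 and -3.81 on the log2 scale in AML replicates 1, 2 and 3. The value of AML replicate 1 leaned on the haemoglobin genes, which are uncertain.

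**Figure D3:**
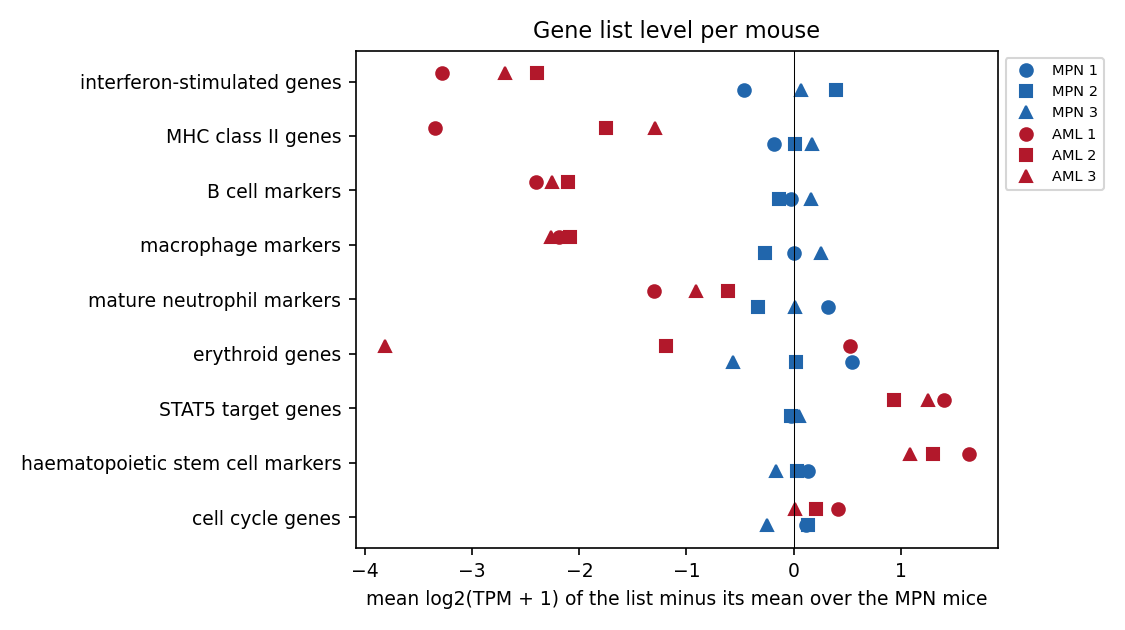
Mean log2(TPM + 1) of the tested members of 9 lists in each mouse, minus the mean over the MPN mice, with MPN in blue and AML in red and replicates 1, 2 and 3 as circle, square and triangle. Erythroid genes, the uncertain haemoglobin genes among them, spanned 0.52 to -3.81 over the AML mice, and B cell markers -2.11 to -2.41.

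Stem cell genes rose. Of 16 haematopoietic stem cell markers, 11 rose, Procr and Ly6a fell and 3 did not pass, with the same counts when adjusted over the list alone (median 1.25, camera adjusted p = 0.00311, adjusted p = 0.366 with an estimated correlation). The Procr call ended with a term for sex, with a log2 fold change of -1.0 against -1.09 without it (adjusted p = 0.0975). Cd34, a surface protein of progenitors, rose from 49.6 ± 8.54 to 338 ± 70.6 TPM, Ifitm1 from 238 ± 44.5 to 2489 ± 304 TPM, and Mecom, a transcription factor gene, from 0.383 ± 0.110 to 10.2 ± 5.20 TPM. Of 10 Hox and Meis genes, 6 rose, Hoxb4 fell and 3 did not pass, with the same counts when adjusted over the list alone (median 1.36, camera adjusted p = 0.0361, adjusted p = 0.589 with an estimated correlation). Hoxb4 had a log2 fold change of -0.64, and its call ended without AML replicate 3 (-0.58, adjusted p = 0.0524), without MPN replicate 1 or 2 (-0.65 and -0.62, adjusted p = 0.0684 and 0.0916) and with a term for sex (-0.75, adjusted p = 0.102). Meis1 rose from 4.51 ± 0.603 to 29.3 ± 5.98 TPM and Hoxa9 from 2.20 ± 0.528 to 19.1 ± 7.82 TPM. The list's call ended with a pseudocount of 5 (adjusted p = 0.0621).

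Of 15 STAT5 target genes, 9 rose, Ccnd1 and Mcl1 fell and 4 did not pass, and 10 rose and 2 fell when adjusted over the list alone (median 1.51, camera adjusted p = 0.00141, adjusted p = 0.366 with an estimated correlation). The Mcl1 call ended without any 1 of the mice other than AML replicate 3 (log2 fold change -0.73 to -0.52, adjusted p of 0.0586 to 0.0932) and with a term for sex (-0.29, adjusted p = 0.349). The cytokine-induced signalling inhibitors Cish and Socs2 rose from 8.29 ± 1.56 to 119 ± 40.0 TPM and from 26.3 ± 2.11 to 179 ± 32.4 TPM. The kinase gene Pim2 rose by 2.32 ± 0.14 (SE) on the log2 scale and Myc from 79.8 ± 6.29 to 243 ± 36.3 TPM. Ccnd1, which encodes cyclin D1, fell from 143 ± 34.4 to 19.5 ± 12.2 TPM, a call that ended with a term for sex (log2 fold change -2.33 against -3.06 without it, adjusted p = 0.0863). Of 14 granulocyte-monocyte progenitor and primary granule genes, 8 rose, 0 fell and 6 did not pass, with the same counts when adjusted over the list alone (median 1.05, camera adjusted p = 0.0280, adjusted p = 0.635 with an estimated correlation). Ctsg, a granule protease, rose from 335 ± 46.1 to 1283 ± 387 TPM and the transcription factor gene Gfi1 from 15.3 ± 3.13 to 52.8 ± 13.7 TPM. The primary granule genes Elane, Prtn3 and Mpo did not pass, with overlapping groups and log2 fold changes of 0.13, 0.39 and 0.60 (adjusted p = 0.816, 0.454 and 0.328). Without AML replicate 2 that list did not pass (adjusted p = 0.206).

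Of 9 stromal and endothelial markers, 7 rose, Kdr fell and 1 did not pass, and 7 rose and 2 fell when adjusted over the list alone (median 2.32, camera adjusted p = 0.0210, adjusted p = 0.366 with an estimated correlation). Igfbp7, a secreted binding protein, rose from 7.18 ± 4.30 to 130 ± 51.6 TPM, Pecam1, an adhesion protein that blood cells also carry, from 28.3 ± 1.80 to 73.8 ± 16.2 TPM, and the basement membrane collagen gene Col4a1 from 1.31 ± 0.468 to 12.1 ± 3.53 TPM. The list's call ended with no filter, where its median was 0.0726 (adjusted p = 0.636), and in the RPKM table (adjusted p = 0.0834).

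**Figure D4:**
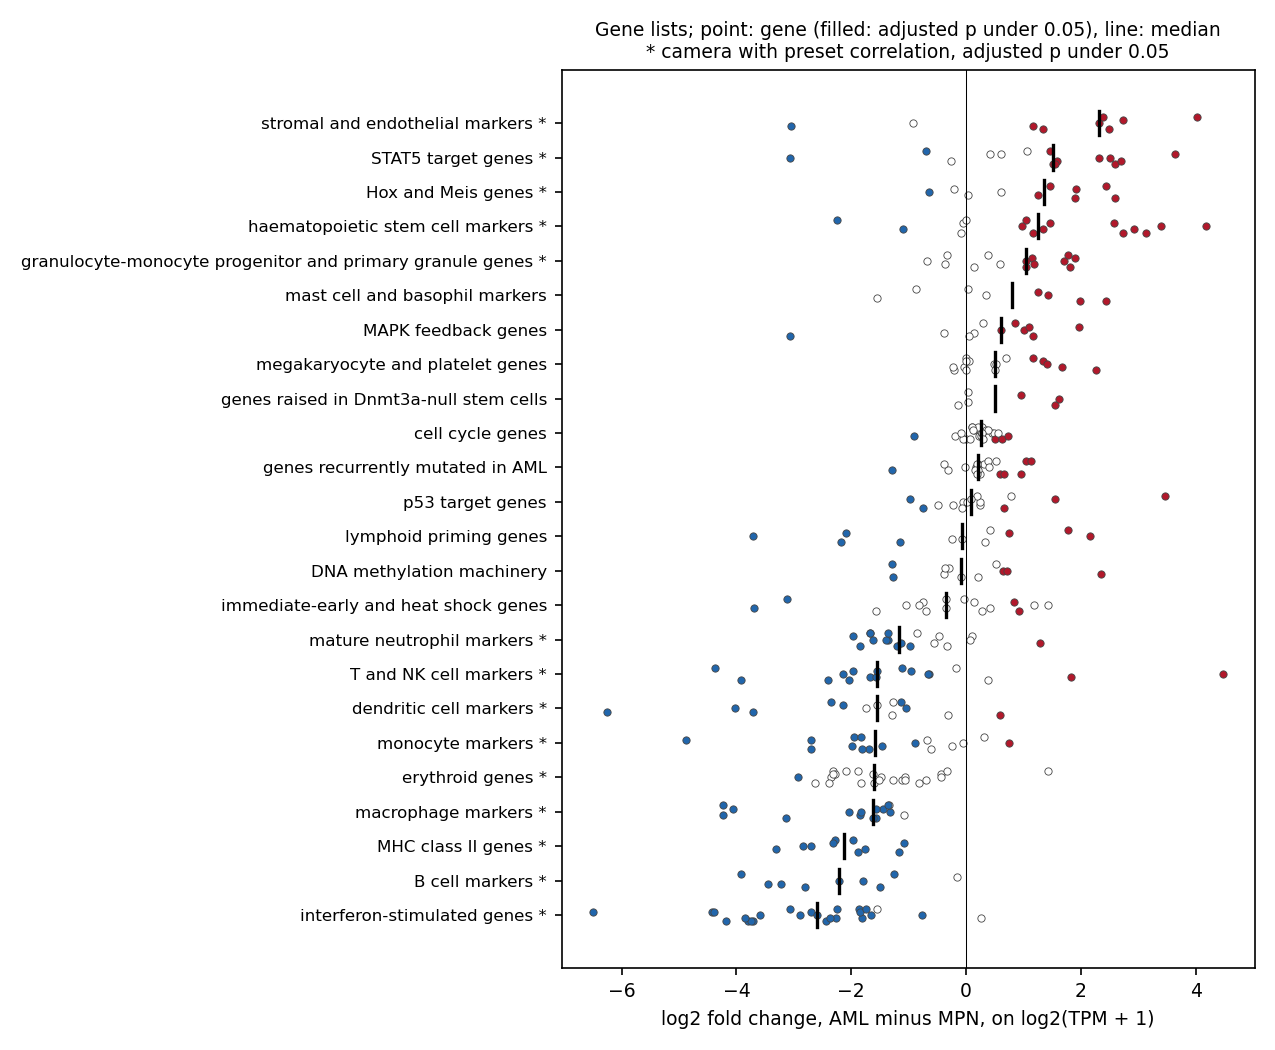
Log2 fold change (AML minus MPN, on log2(TPM + 1)) of each tested member of the 24 lists, filled where the limma adjusted p was under 0.05 (red for higher, blue for lower in AML), with the list's median as a line. The medians ran from -2.59 for interferon-stimulated genes to 2.32 for stromal and endothelial markers, and an asterisk marks the 14 lists past the camera threshold at the preset correlation.

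The other 10 lists did not pass camera. In the DNA methylation machinery, 3 of 11 genes rose, 2 fell and 6 did not pass, with the same counts when adjusted over the list alone (median -0.09, mean 0.07, test direction down, adjusted p = 0.379). Dnmt3b, the other de novo methyltransferase, rose from 9.45 ± 1.81 to 53.8 ± 19.3 TPM (log2 fold change 2.35 ± 0.26 SE, adjusted p = 0.00101), and Apobec1 fell from 25.5 ± 3.45 to 10.3 ± 3.31 TPM. The other gene that fell was Dnmt3a itself, whose alleles differ between the groups by design. Of 6 genes known to be raised in Dnmt3a-null stem cells, 3 rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.134), and these were Cdkn1a, Runx1 and Gata3 with log2 fold changes of 1.56, 0.96 and 1.62. With a term for sex this list passed (median 0.61, 3 rose, 0 fell, adjusted p = 0.0411). Vasn stood at 15.5 ± 3.82 against 17.5 ± 6.34 TPM (adjusted p = 0.760). Of 21 genes recurrently mutated in AML, 5 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.141), among them Idh2, which rose from 106 ± 2.08 to 235 ± 27.5 TPM. The 1 that fell was again Dnmt3a, so this fall belongs to the design. Of 27 cell cycle genes, 3 rose, 1 fell and 23 did not pass, and 1 rose and 0 fell when adjusted over the list alone (median 0.26, camera adjusted p = 0.196). Without AML replicate 3 the cell cycle list passed (median 0.338, 5 rose, 0 fell, adjusted p = 0.0313). Mcm6, a replicative helicase subunit, rose by 0.72 ± 0.15 (SE) on the log2 scale, and by 0.50 with a term for sex, where it did not pass (adjusted p = 0.168).

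Of 16 megakaryocyte and platelet genes, 5 rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.190), with Nfe2 rising from 58.1 ± 10.6 to 188 ± 44.4 TPM and Itga2b from 8.34 ± 3.42 to 45.7 ± 25.7 TPM. With array weights this list passed (median 0.67, 6 rose, 0 fell, adjusted p = 0.0450). The Itga2b call ended with a term for sex, with a log2 fold change of 1.82 against 2.26 without it (adjusted p = 0.0934). Of 8 mast cell and basophil markers, 4 rose and 0 fell, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.267), with the protease gene Cpa3 rising from 8.25 ± 2.77 to 49.5 ± 15.8 TPM. Of 11 lymphoid priming genes, 3 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.196). Cd27 rose by 2.16 and Il7r fell by 2.18 on the log2 scale. Of 11 MAPK feedback genes, 6 rose and 1 fell, and 6 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.290), with Etv5 at a log2 fold change of 1.97 and Spry1 at 1.10. Both calls ended with a term for sex (log2 fold change 2.05 and 0.85, adjusted p = 0.0856 and 0.170), and that of Spry1 also without MPN replicate 2 (0.0509). Of 17 immediate-early and heat shock genes, 2 rose and 2 fell, and 3 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.117), with the heat shock gene Hspa1b falling from 307 ± 201 to 22.1 ± 16.8 TPM. The Hspa1b call ended with a term for sex, with a log2 fold change of -3.58 against -3.69 without it (adjusted p = 0.102). This list passed without AML replicate 3 (median -0.77, 0 rose, 7 fell, adjusted p = 0.00532) and with array weights (2 rose, 7 fell, adjusted p = 0.0231). Of 15 p53 target genes, 3 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.976), with Perp rising from 0.387 ± 0.224 to 17.0 ± 12.1 TPM. The median of the p53 list was 0.09, and it was -0.02 under median scaling and under quantile normalization.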

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

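The fit with a term for sex was chosen after seeing the data, and the other alternatives before. Over the main results and all alternatives, 112 values kept their direction and side of the threshold or their count within 1.5 times, 14 moved further and 4 lost the call. Of the other named genes and lists, 2037 kept theirs, 137 lost the call, 29 gained it and 16 reversed, and the cause was not tested for any. With a pseudocount of 5, 970 genes met the 2-fold screen, since it shrinks low genes. With array weights, 2131 genes were lower in AML. With a term for sex, which sets the male AML mouse alone against the MPN mice, 1208 genes passed, 673 higher and 535 lower, and 1080 of the 3678 calls were kept. With an estimated correlation 0 lists passed. Leaving out 1 mouse at a time, which leaves fewer samples, gave 2009 to 3705 genes, 1291 to 2303 higher and 718 to 1402 lower, with 1570 to 2061 genes in the 2-fold screen and 13 to 16 lists. The log2 fold change ranged from -1.35 to -1.22 for Dnmt3a, from 0.46 to 0.71 for Flt3 and from -0.38 to -0.19 for Kit. Flt3 missed the threshold under median scaling at 0.45. The p53 target list turned in its test direction or median, with medians of 0.0537 with a pseudocount of 5, -0.0204 under median scaling, -0.0194 under quantile normalization, -0.0382 with array weights, 0.0922 with camera on ranks and 0.0277 to 0.112 on leaving out 1 mouse, where the test turned without AML replicate 1 and without MPN replicate 1. The mast cell and basophil list turned with no filter (0.0223) and with a term for sex (0.0957), and Vasn with a term for sex (0.0767) and without AML replicate 2 or MPN replicate 1, within a range of -0.445 to 0.0800 on leaving out 1 mouse. The term for sex also turned the cell cycle list (0.0424), the immediate-early and heat shock list (0.521), Ddx3y (0.115) and Eif2s3y (0.155). No result among these reversals had passed its threshold in the main analysis. With RPKM values, 2995 of the 3168 calls present were kept and 6 changed sign. No paired analysis was possible because replicate numbers were given in accession order and name no shared litter or day. Depth is known only relative to the other libraries, and low values such as 0.04 TPM rest on few reads.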

Other observations

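The AML mice differed among themselves in genes of red cells and of antigen presentation. The mean of the 25 tested erythroid genes, on the log2(TPM + 1) scale and relative to the MPN mice, was 0.52 in AML replicate 1, -1.20 in AML replicate 2 and -3.81 in AML replicate 3, while the MPN mice lay between -0.57 and 0.55. The MHC class II list went the other way, at -3.35, -1.76 and -1.29 in AML replicates 1, 2 and 3, and the invariant chain gene Cd74 stood at 2599, 7335 and 11929 TPM there against 21076 to 24342 TPM in MPN. The erythroid mean of 0.52 in AML replicate 1 leaned on haemoglobin genes, whose values are uncertain. Hbb-bs stood at 591 TPM there against 0, 0 and 196 TPM in the MPN mice. Hbb-b2 and Hbb-bt had the same values in every library, 769 TPM in AML replicate 1, so they count 1 measurement more than once. Cd74, these haemoglobin genes and the cyclin D and Bcl2 family genes below were chosen after their values were seen.

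Cyclin D genes went apart between the groups. Ccnd2 rose from 38.9 ± 0.746 to 111 ± 22.2 TPM (limma adjusted p = 0.00101) while Ccnd1 fell from 143 to 19.5 TPM, and Ccnd3 did not pass, at 227 ± 25.4 against 272 ± 25.4 TPM (adjusted p = 0.146). The anti-apoptotic gene Bcl2 rose from 9.56 ± 1.21 to 46.8 ± 17.1 TPM (adjusted p = 0.00129), while Mcl1, of the same family, fell from 299 ± 15.9 to 189 ± 50.5 TPM (adjusted p = 0.0282). The Mcl1 call ended without any 1 of the mice other than AML replicate 3 (adjusted p of 0.0586 to 0.0932) and with a term for sex (0.349), and that of Ccnd1 ended with a term for sex (0.0863).

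The tests of sex, of the immune lists, of interferon-stimulated genes and of Kit below were chosen after the result was seen, and those of the splits, the sequencing run, the neighbourhood of Dnmt3a, the chromosomes and the germline and imprinted genes before. For the neighbourhood of Dnmt3a and the imprinted genes, the rule that an interval must also stay within the bound was added after the result was seen. The number of genes that passed, 3678, was reached by 1 of the 10 splits of the 6 mice into 3 and 3. The highest of the others gave 0 (369 at an unadjusted p under 0.05). Those splits mix AML and MPN mice, so the difference between the groups widens the spread within each side and lowers the count. Their 0 is therefore no measure of what chance gives, and 10 splits are too few for a share under 0.05. The male AML mouse showed a median of 0.791 of the change of the female AML mice over 1961 genes. Each MPN mouse was also set in its place against the other MPN mice, over 2151, 2049 and 1963 genes chosen anew by the 2-fold screen. The MPN mice showed 0.105, -0.00199 and -0.0297, where the male AML mouse showed 0.7874, 0.7902 and 0.7955. Sex stays open, because 1 male AML mouse carries this test and the fit with a term for sex. The sequencing run is argued against by 2277 genes within 1 run. Variants carried along with Dnmt3a could raise the share of called genes nearby. A share well above that elsewhere is argued against by 8 called genes among 32 within 10 Mb. This was 25% (exact 95% interval 11.5% to 43.4%) against 29.9% elsewhere (Fisher's exact p = 0.700). Variants that act on only a few nearby genes would hardly move this share and stay open. Those acting on distant genes or on proteins were not tested and also stay open. Gain or loss of a whole autosome in most cells of an AML mouse is argued against by the chromosome medians. The farthest, on chromosome 14, lay 0.0939 from that of all genes on the log2 scale. Changes of chromosome segments, of the sex chromosomes or in a small part of the cells were not tested and stay open. Dnmt3a genotype, Cre and the disease stage also stay open, since the design joins them.

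The fall of the immune and interferon lists may reflect fewer mature cells behind the beads in AML. B cell markers fell further than neutrophil markers, with a median -1.05 from theirs (95% bootstrap interval -2.39 to -0.12). That interval resamples genes, which vary together, and not mice. Relative to the MPN mice, the B cell mean was -2.41, -2.11 and -2.26 in AML replicates 1, 2 and 3. The neutrophil mean was -1.30, -0.61 and -0.91. A like loss of all mature cells stays open, because neutrophil transcripts made by cells that stayed would fall less. For the interferon-stimulated genes, the test was redesigned after a first version, the difference of their median from that of the macrophage, B, T and dendritic cell markers (-0.99, interval -2.03 to -0.28), had been seen. In the second version 13 of these 54 markers fell as far as the median interferon-stimulated gene, so a loss of the cells that carry these transcripts and a lower interferon response cannot be told apart. Between MPN mice the interferon-stimulated genes spanned 0.854 on the log2 scale and the markers 0.262. The titles name Cre in the AML mice only, so the Cre construct also stays open.

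The rise of the STAT5 target and stem cell lists could come from a larger share of progenitors once mature transcripts are lost. Kit did not rise with them, at a log2 fold change of -0.31 (-0.57 to -0.06, 2 standard errors) where the STAT5 median was 1.51. The cell cycle median was 0.26 (0.338 without AML replicate 3, where that list passed), while the median of all genes was 0.13. Because the cells were collected by c-Kit, Kit cannot report their share freely, and cell cycle genes are not markers of progenitors. A larger share of progenitors therefore stays open. A change in which progenitors were present was not tested and also stays open.

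Lower Dnmt3a may raise germline genes that DNA methylation silences. Of 16 such genes only 1, Sycp1, was expressed enough to be tested, at a log2 fold change of -0.57. The others, as far as they were measured, did not reach 1 TPM in 3 libraries, so none rose to that level in all AML mice. A smaller rise is neither shown nor excluded. Camera gave a p of 0.370, which rests on this 1 gene and is no test of the group. Of 24 imprinted genes 12 were tested, of which 3 rose and 1 fell. Their median was -0.02 (95% bootstrap interval -0.20 to 0.77), and camera gave a p of 0.972, so a shift of the group is neither shown nor excluded.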
